A study of Arabidopsis thaliana with 4 samples.

How the data were processed

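Total RNA from the vegetative part of Arabidopsis thaliana was measured on 4 two-colour Agilent arrays. Each array set wild-type Col-0 against the triple mutant shr-2 scl23-1 scr-5 in the same background. Per the labels, there were 2 replicates of the genotype pair, each hybridised once with the mutant in Cy5 and once with the dyes exchanged. The numbering in the descriptions was read as both arrays of a replicate using the same pair of extracts, so they were averaged and counted as 1 replicate, which leaves n = 2. The design text could also be read as 4 biological pairs, and the labels do not settle it. With 4 arrays and no replicate block, 6565 genes passed in place of 3377. The design text calls the replicates biological, without saying from which plants or cultures they came, so p-values measure the spread between these 2 pairs. The file headers place all 4 arrays on 1 slide in 1 scan, so slide and scan do not separate arrays.

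The deposited scanner files hold, per spot, the mean intensity of each channel and its local background, both unprocessed, from Agilent Feature Extraction 10.7.3.1 per the file headers. They also hold processed intensity values, which the software had background-subtracted and dye-normalised with LOWESS per the file headers, and a log10 ratio of red over green made from these. The authors' deposited value table holds log2 ratios. Set against the scanner files, its columns follow the log2 ratio of the processed signals, turned to mutant over wild type on every array, closely but not exactly, with median differences of 0.026, 0.019, 0.017 and 0.015. Its column medians were -0.061, 0.07, -0.067 and 0.052, and the step behind the differences is not given in the sources used here. Flags for spots well above background, saturated spots and outliers were used as other columns of the deposited scanner files.

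Background was corrected with normexp (offset 50) on mean signal and local background median, and each array was normalised by loess (span 0.3, control spots with weight 0) in limma 3.58.1 under R 4.3.3. Log2 ratios were turned to triple mutant over wild type. Control spots and spots flagged as outliers were left out, and spots of a probe were averaged. Of 43603 probes, 33840 were named through an unversioned accession in the RefSeq gene table of assembly TAIR10.1, 1840 through a locus name and 170 through another accession. A further 452 probes matched several loci and 7301 matched none, and these were not used for genes. The array design carries the build ath1:Jan2004 per the file headers, so no coordinate from the gene table is printed, and that table gave names and gene order alone. A gene was tested if its probe was well above background in at least 1 genotype's channel on all 4 arrays. The brightest such probe stood for the gene, which left 20530 genes.

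The 2 replicate values per gene were tested against 0 with lmFit and eBayes, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Errors are standard errors (SE) of that fit. With 1 residual degree of freedom per gene, the moderated spread leans on the prior, which had 3.47 degrees of freedom and an SD of 0.135. Genes saturated on all arrays of 1 genotype, or not well above background there, have a bound in place of a fold. For these the bright genotype's mean after loess and Aquantile was set against the dim one's, raised where needed to the lowest signal well above background on that array.

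Before the data were examined, 35 gene lists, the tests, the alternatives and the rule for named genes were written down. List members were written from memory as symbol and locus, and 9 of 467 were dropped because the gene table did not pair them. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. The named genes are the 3 targeted genes, the 12 highest and 12 lowest log2 ratios among genes past the threshold with 1 sign on all 4 arrays, and up to 4 members of each list with the smallest p. Other members and neighbours named below were chosen after their values were seen.

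The procedure was tested on simulated data, with 50 genes changed at each of 4 sizes among the 20530. At a true log2 ratio of 0.5 the test called 3 of 50, at 1 it called 39 of 50, and at 2 and at 4 it called 50 of 50. It also called 15 of 20315 unchanged genes, which made up 8.82% of its calls, more than the 5% the threshold aims at. In the data 16.45% of genes passed, a far larger share than was changed in the simulation. The adjustment depends on that share, so these rates do not carry over directly to the data. A simulated list shifted by 1 gave adjusted p = 3.86e-34 by camera with the preset correlation. With an estimated correlation it gave adjusted p = 0.972, so there, with 2 replicates, the latter missed a shift of that size. Simulated genes varied independently. The simulation therefore does not show whether the preset correlation gives p-values that are too small where list members vary together. The precision of every value is limited by the number of arrays. Alternatives covered background, normalisation within and between arrays, the authors' value table, the probe filter, the probe rule, 4 arrays with and without the replicate block, each dye orientation, moderation, single arrays and replicates left out, the set test and the threshold. A further 4 were chosen after seeing the data.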

Results

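The data are 4 two-colour arrays of the vegetative part of seedlings at growth stage 1.04, grown on MS medium in 16 h light and 8 h dark at 22 °C. They compare wild-type Col-0 with a triple mutant in SHR, SCL23 and SCR, 3 genes for GRAS-family transcription factors. SHR and SCR are known for their roles in forming the endodermis and the bundle sheath. Median spot signals ran from 198.7 to 263.1 in green and from 421.8 to 638.8 in red, over median local backgrounds of 34 and of 44 to 57. Between 71.0% and 78.6% of spots were well above background in a channel. Across genes, the log2 ratios of the arrays of one replicate correlated at 0.836 and 0.863, and the means of both replicates at 0.816. Single arrays of different replicates correlated at 0.814 and 0.81 with the same dyes, and at 0.701 and 0.694 with dyes swapped. Genes are not independent replicates in these correlations. All log2 ratios below are triple mutant over wild type, with SE over n = 2 replicates.

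The first question is whether the 3 mutated genes themselves had less transcript. SHR (AT4G37650) fell by 1.71 on the log2 scale (SE 0.09, adjusted p = 0.00342), SCR (AT3G54220) fell by 1.22 (SE 0.09, adjusted p = 0.00534) and SCL23 (AT5G41920) fell by 1.89 (SE 0.11, adjusted p = 0.0038). Each was lower on all 4 arrays, from -2.11 to -1.42 for SHR, from -1.42 to -1.12 for SCR and from -2.27 to -1.43 for SCL23. All 3 stayed well above background in the mutant on all 4 arrays. On the array design's build ath1:Jan2004, the probes lie at chromosome 4, 17693350 to 17693409 (SHR), chromosome 3, 20083542 to 20083601 (SCR), and chromosome 5, 16798331 to 16798390 (SCL23). A dimmer SCR probe at 20082025 to 20082085 gave -0.44, and a dimmer SCL23 probe at 16798047 to 16798106 gave -1.44. Where the mutations lie relative to these probes is not given in the sources used here, so the ratios do not measure how much functional transcript was left. The SCR value moved to -0.83 with both probes averaged. The sizes also depended on the processing. For SHR, SCR and SCL23 the authors' value table gave -2.09, -1.42 and -2.19, and median centring gave -1.505, -1.01 and -1.68.

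The second question is which other genes differed between the genotypes. The genes with the highest ratios were led by genes of phosphate starvation. PS2, a phosphatase gene induced by low phosphate, rose by 5.24 (SE 0.22, adjusted p = 0.00239), with its lowest probe at 3.38 and saturation in the mutant on 1 of 4 arrays. The non-coding RNA AT4, saturated in the mutant on 2 of 4 arrays, rose by 4.17 (SE 0.11), the galactolipid synthase gene MGD3 by 3.95 (SE 0.30), the phosphate sensor gene SPX1 by 3.88 (SE 0.19) and the acid phosphatase gene PAP17 by 3.22 (SE 0.13). SRG3 (AT3G02040), for a glycerophosphodiester phosphodiesterase, rose by 3.37 (SE 0.25), with a second probe at 1.37 and saturation in the mutant on 1 of 4 arrays. LSU1 and SDI1, both known as markers of sulfur deficiency, rose by 3.82 (SE 0.10, second probe 1.49) and 3.17 (SE 0.38), and the anthocyanin gene DFR rose by 3.32 (SE 0.10). AT5G20790 rose by 3.85 (SE 0.15) and MRD1 by 3.68 (SE 0.14). AT1G54040, which encodes the epithiospecifier protein of glucosinolate breakdown, was saturated in the mutant on all 4 arrays and was at least 24.1-fold higher there on the probe used (adjusted p = 0.00172), with its probes from 3.73 to 5.69 on the log2 scale.

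The lowest ratios were those of RPS15AD, a ribosomal protein gene, which fell by 6.67 (SE 0.11, adjusted p = 0.00172), and of CCD1, for a carotenoid cleavage dioxygenase, which fell by 5.71 (SE 0.15). Other genes that fell were AT1G73490 with -5.69 (SE 0.15), AT2G04378 with -5.01 (SE 0.18), AT3G47250 with -4.81 (SE 0.11), the phospholipase gene PLC8 with -4.26 (SE 0.11) and AT4G02540 with -4.15 (SE 0.20). The exocyst gene EXO84B fell by 4.21 (SE 0.15), with the mutant channel well above background on 2 of 4 arrays. The remaining 4 were AT4G11290 with -3.84 (SE 0.09), the iron-sulfur protein gene NEET with -3.64 (SE 0.16), CDT1 (AT1G52827) with -3.54 (SE 0.10) and AT5G02160, saturated in wild type on 2 of 4 arrays, with -3.53 (SE 0.13). Saturation makes such ratios imprecise beyond their SE. Each of these genes with 2 tested probes fell less on the other probe, by more than 1 on the log2 scale. Those probes gave -0.35 for RPS15AD, -0.68 for AT4G11290, -1.33 for CDT1 and -1.40 for AT5G02160. They gave -1.98 for PLC8, -2.97 for AT3G47250, -3.25 for AT2G04378 and -3.41 for AT1G73490. CCD1, EXO84B, AT4G02540 and NEET had 1 tested probe each, so no second probe checks their ratios.

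**Figure D1:**
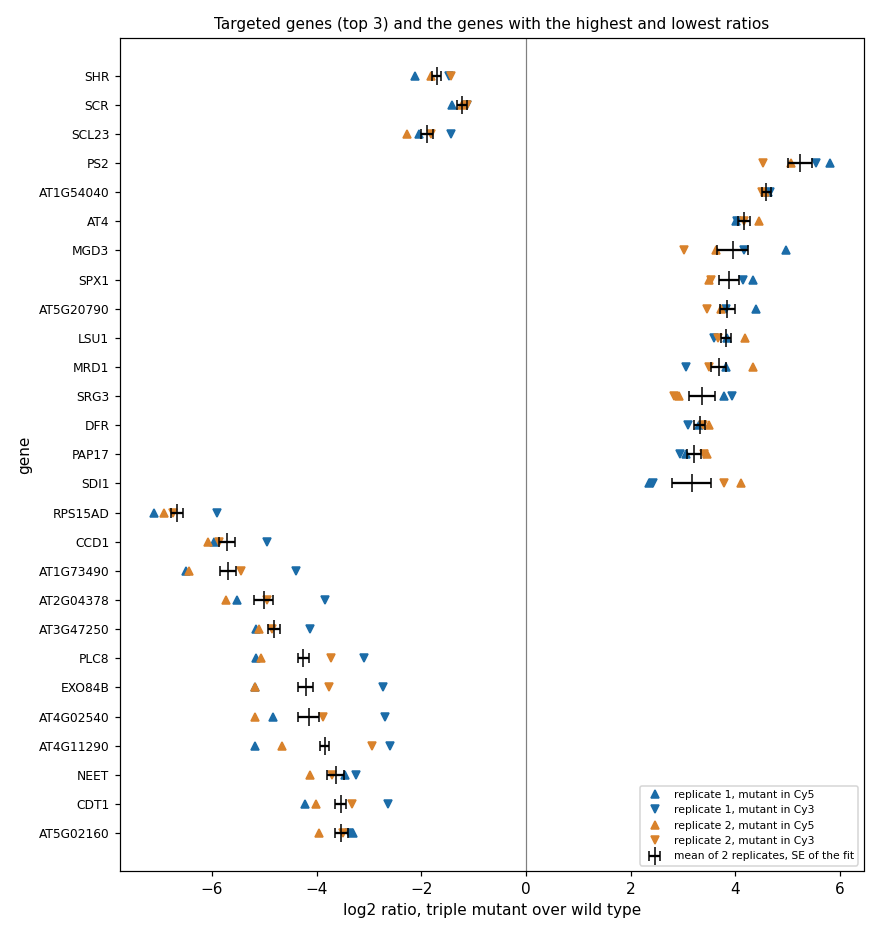
Log2 ratio of triple mutant over wild type (x axis) for the 3 targeted genes and the 12 highest and 12 lowest genes (y axis). Triangles are the 4 arrays, black bars the mean of 2 replicates with the SE of the fit. All 4 arrays of each gene lie on one side of 0, which was a condition for choosing the highest and lowest genes. Means run from -6.67 for RPS15AD to 5.24 for PS2.

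In all, 3377 of 20530 genes passed the threshold with limma, 1976 of them higher and 1401 lower in the mutant. Of these, 521 were at least 2-fold higher and 341 at least 2-fold lower. A count with no test found 275 genes at least 2-fold higher and 173 at least 2-fold lower on each of the 4 arrays. Median centring of the arrays in place of loess moved the median of all genes to 0.15 and the share of calls that were higher from 58.5% to 74.1%. The count of calls fell to 1395 without the array of replicate 1 with the mutant in Cy5, and rose to 5703 with 4 arrays and a replicate block.

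Genes of phosphate starvation rose together: all 15 measured members passed over all genes, and 15 adjusted over the list alone, with a median of 2.102. Besides those above, the transporter gene PHT1;4 rose by 2.34 (SE 0.09, adjusted p = 0.00228) and the sulfolipid gene SQD1 by 1.85 (SE 0.09). The list gave adjusted p = 2.56e-12 by camera and adjusted p = 0.692 with an estimated correlation. No list passed with an estimated correlation, where the smallest adjusted p by camera was 0.692. That test rests on 1 residual degree of freedom and missed a shift of 1 in a simulation of independent genes. The flavonoid list below also gave 0.692 there with an estimated correlation of -0.053, so positive correlation of its members does not account for that value. A failure to pass that test thus says little about a list. In the data the estimated correlation was 0.162 for this list and 0.621 for the sulfur list below, against the preset 0.01. It was below 0 for some other lists that passed, such as suberin with -0.091 and indole glucosinolate and camalexin with -0.077. Each estimate rests on 1 residual per gene and is imprecise. Neither the simulation nor these estimates settle which p-values to trust.

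Sulfur genes were higher too. Of 20 members on sulfate uptake, assimilation and sulfur deficiency, 13 rose and none fell. Adjusted over the list alone, 15 were higher and 1 lower. The glucosidase gene BGLU28 rose by 2.96 (SE 0.25, adjusted p = 0.00688), the reductase gene APR1 by 1.57 (SE 0.12) and the transporter gene SULTR1;2 by 1.49 (SE 0.13, second probe 0.23). Camera gave the sulfur list adjusted p = 4.9e-06, and adjusted p = 0.703 with an estimated correlation. Of 11 iron deficiency genes, 9 rose (10 adjusted over the list alone), including the nicotianamine synthase gene NAS4 by 1.73 (SE 0.15, adjusted p = 0.00766), the ferric reductase gene FRO2 by 1.31 (SE 0.08) and the iron transporter gene IRT1 by 0.90 (SE 0.10). That list gave adjusted p = 1.07e-05, and adjusted p = 0.692 with an estimated correlation. Of 4 ferritins, 1 fell, FER4 by 1.40 (SE 0.28, adjusted p = 0.0394); adjusted over the list alone, 1 was higher and 2 lower, and the list did not pass (adjusted p = 0.253).

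The list of root markers was higher in the same arrays, as a fact to set beside these 3 nutrient groups. Of 8 root markers 2 rose, the nitrate transporter gene NRT2.1 by 2.19 (SE 0.17, adjusted p = 0.00618) and the glucosidase gene PYK10 by 0.48 (SE 0.09, adjusted p = 0.0347), and 7 passed adjusted over the list alone. PYK10 was saturated in some spots and gave -0.08 on the arrays with the mutant in Cy5. The root list had a median of 1.35 in replicate 1 and 0.44 in replicate 2 (adjusted p = 0.0103, and adjusted p = 0.692 with an estimated correlation), and it lost its call when both channels had to be well above background. With processed signals and loess its median was 3.09, against 2.39 for the phosphate list.

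Genes of carbohydrate storage and pigment were higher, and genes known to be induced by sugar starvation were lower. Of 19 flavonoid and anthocyanin genes 12 rose and none fell (15 adjusted over the list alone). UGT79B1, an anthocyanin glycosyltransferase gene, rose by 2.96 (SE 0.09, adjusted p = 0.00174), LDOX by 1.93 (SE 0.09) and TT7 by 1.76 (SE 0.09). Flavonoid genes as a list gave adjusted p = 1.22e-09, and adjusted p = 0.692 with an estimated correlation. Of 12 genes of starch and sucrose metabolism and transport, 8 rose (8 adjusted over the list alone). The plastid glucose-phosphate transporter gene GPT2 rose by 2.81 (SE 0.17, adjusted p = 0.00383), the starch synthesis gene APL3 by 1.68 (SE 0.08), SUS3 by 1.48 (SE 0.10) and GBSS1 by 0.97 (SE 0.10). That list gave adjusted p = 0.000345, and adjusted p = 0.692 with an estimated correlation. Of 7 sugar starvation genes, 6 fell and 1 rose, with the same counts adjusted over the list alone. SEN1 fell by 2.19 (SE 0.12, adjusted p = 0.00323), TPS11 fell by 1.62 (SE 0.10) and DIN10, saturated in wild type on 2 of 4 arrays, fell by 1.195 (SE 0.09), while DIN2 rose by 1.06 (SE 0.12, lowest probe 0.37). ASN1, which also fell, gave -1.67 in replicate 1 and -4.10 in replicate 2, with its highest probe at -1.48. The list gave adjusted p = 0.000633, and adjusted p = 0.692 with an estimated correlation.

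Of 13 genes of indole glucosinolate and camalexin synthesis 6 rose (8 adjusted over the list alone), with CYP83B1 up by 1.32 (SE 0.10, adjusted p = 0.00536), the camalexin gene PAD3 by 1.13 (SE 0.09) and CYP79B2 by 1.04 (SE 0.14). The list gave adjusted p = 0.000633, and adjusted p = 0.692 with an estimated correlation. Of 14 aliphatic glucosinolate genes 7 fell and 2 rose; adjusted over the list alone, 7 were lower and 4 higher. The regulator MYB29 fell by 1.16 (SE 0.08, adjusted p = 0.00538) and CYP79F1 by 0.81 (SE 0.09), while MAM3 rose by 1.06 (SE 0.09). That list gave adjusted p = 0.047, and adjusted p = 0.692 with an estimated correlation, and it lost its call under 14 of 20 other settings. The difference between the 2 classes was not tested.

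Of 19 genes of salicylic acid and immunity 13 rose and 1 fell (16 and 1 adjusted over the list alone). WRKY54 rose by 1.58 (SE 0.09, adjusted p = 0.0038), WRKY38 by 1.48 (SE 0.12), FMO1 by 1.32 (SE 0.10) and SARD1 by 0.89 (SE 0.09). PR2, a pathogenesis-related gene, was the member that fell, by 0.86 (SE 0.09, adjusted p = 0.00915). The list gave adjusted p = 4.9e-06, and adjusted p = 0.692 with an estimated correlation. Of 21 jasmonate genes 6 rose and 6 fell (6 and 7 adjusted over the list alone), and the list did not pass (adjusted p = 0.594), with a median of 0.02 and a mean of -0.13. The synthesis genes AOC2 and AOS rose, by 1.28 (SE 0.13, adjusted p = 0.0098) and 0.72 (SE 0.12). The repressor genes JAZ9 and JAZ7 fell, by 1.74 (SE 0.08, adjusted p = 0.00283) and 1.14 (SE 0.10), as did TAT3, by 2.21 (SE 0.21, second probe -0.52).

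Several cytokinin response genes were lower in the mutant. Of 16 genes of cytokinin response and metabolism 8 fell and 1 rose (10 and 3 adjusted over the list alone). All were type-A response regulators except CKX4 and CKX6. ARR7 fell by 2.105 (SE 0.10, adjusted p = 0.0028), ARR6 by 1.70 (SE 0.09), ARR5 fell by 1.297 (SE 0.08) and ARR9 by 1.25 (SE 0.08), and the cytokinin oxidase gene CKX6 rose by 0.81 (SE 0.12). ARR5 (AT3G48100) lies in a region of chromosome 3, described below, where sequence variants that change probe binding could be neither excluded nor shown. As a group, the cytokinin genes gave adjusted p = 0.0014, and adjusted p = 0.692 with an estimated correlation. Of 19 auxin response genes 5 fell and 1 rose (5 and 3 adjusted over the list alone), among them IAA3, which fell by 0.69 (SE 0.09, adjusted p = 0.0141), and the list did not pass (adjusted p = 0.0961). Of 17 gibberellin genes 3 rose (6 higher and 1 lower adjusted over the list alone), led by the receptor gene GID1B, by 0.87 (SE 0.10, adjusted p = 0.0118). The gibberellin list did not pass by camera (adjusted p = 0.115), which looks for a shared direction. It did pass by mixed fry, which allows both directions (adjusted p = 0.0224).

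Of 5 trichome and epidermis genes 3 fell (3 adjusted over the list alone): GL2 by 1.34 (SE 0.13, adjusted p = 0.00889), GL1 by 1.27 (SE 0.09) and TRY by 0.66 (SE 0.13), all regulators of trichome formation. For the trichome list, adjusted p = 0.00757, and adjusted p = 0.692 with an estimated correlation. Of 11 genes of flowering and phase change 3 fell and 1 rose (5 and 1 adjusted over the list alone). SPL4 fell by 1.56 (SE 0.09, adjusted p = 0.0038), SEP3 by 1.29 (SE 0.14, highest probe -0.58) and SPL3 by 0.98 (SE 0.10), while the floral repressor FLC rose by 0.73 (SE 0.15, adjusted p = 0.0432). That list gave adjusted p = 0.00258, and adjusted p = 0.703 with an estimated correlation. The meristem genes KNAT1 and KNAT6 rose by 0.71 (SE 0.09, adjusted p = 0.0141) and 0.63 (SE 0.08), 2 of 5 in their list over all genes and 2 adjusted over the list alone. The meristem list did not pass (adjusted p = 0.0642), though it did under 7 of 20 other settings. Of 10 leaf polarity genes 1 fell, CNA by 0.61 (SE 0.12, adjusted p = 0.0366), with 1 adjusted over the list alone and list adjusted p = 0.972.

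Among genes close to the known roles of the mutated genes, the pathway and endodermis lists did not pass and the suberin list did. Of 10 further SHR-SCR pathway genes 2 fell and 1 rose (3 and 3 adjusted over the list alone): SNE by 1.05 (SE 0.09, adjusted p = 0.00688), JKD by 0.52 (SE 0.10) and, upwards, MGP by 0.59 (SE 0.10). The list did not pass by camera (adjusted p = 0.936), with a median of 0.12 and a mean of -0.01. Camera looks for a shared direction, and members of this list changed both ways, so it does not show the pathway to be unchanged. Mixed fry gave the list adjusted p = 0.0678. Of 7 genes of the endodermal barrier 1 rose, the regulator MYB36 by 0.62 (SE 0.10, adjusted p = 0.0232), with a second probe at -0.02, also 1 adjusted over the list alone, and the list did not pass (adjusted p = 0.318). Of 12 genes of suberin and its transport 8 rose (8 higher and 1 lower adjusted over the list alone), with CYP86A1 up by 1.13 (SE 0.08, adjusted p = 0.00581), CYP86B1 by 0.66 (SE 0.09) and GPAT5 by 0.62 (SE 0.09). The suberin list gave adjusted p = 0.00262, and adjusted p = 0.692 with an estimated correlation, and lost its call with median centring. These suberin genes are also expressed in roots, whose markers were higher in the same arrays.

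The cell cycle lists had small medians, from -0.12 for G2 to M phase to 0.03 for CDK inhibitors and D-type cyclins. None of 18 genes of G2 to M phase passed alone, over all genes or adjusted over the list alone, yet the list lay lower, with a median of -0.12 (adjusted p = 0.0342, and adjusted p = 0.703 with an estimated correlation). It lost its call under 3 of 20 other settings, including median centring, and its median ranged from -0.18 to 0.06 over them. By replicate its median was -0.05 and -0.18. None of 15 genes of DNA replication and S phase passed, over all genes or adjusted over the list alone (list adjusted p = 0.876). Of 15 CDK inhibitor and D-type cyclin genes 2 fell and 1 rose (3 and 2 adjusted over the list alone; list adjusted p = 0.936), with SMR5 up by 0.98 (SE 0.15, adjusted p = 0.0243), and KRP7 and CYCD3;2 down by 0.52 (SE 0.09) and 0.57 (SE 0.10).

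For light harvesting and photosynthesis the result depended on the arrays used. Of 23 members 7 were lower past the threshold and none higher (14 adjusted over the list alone), and the list gave adjusted p = 1.02e-06, and adjusted p = 0.692 with an estimated correlation. Its median was -0.57 over both orientations and 0.21 on the arrays with the mutant in Cy3 alone, of which replicate 1 gave 0.67 and replicate 2 gave -0.23. The median was -0.29 in replicate 1 and -0.77 in replicate 2, and the call was also lost without the array of replicate 1 with the mutant in Cy5. Only 4 of the 23 were unsaturated on every array, and with all saturated genes left out, a setting chosen after seeing the data, the list did not pass (adjusted p = 0.111). GLK2, a regulator of chloroplast genes with no saturated spot, fell by 0.61 (SE 0.10, adjusted p = 0.0274). LHCB2.1 fell by 1.38 (SE 0.30, adjusted p = 0.0472), with a second probe at -3.45. Of 11 senescence genes 2 fell (3 adjusted over the list alone), NAP by 1.17 (SE 0.14, adjusted p = 0.0137) and SAG13 by 0.83 (SE 0.10). That list gave adjusted p = 0.0214, and adjusted p = 0.692 with an estimated correlation, and lost its call with median centring and with the mutant in Cy5 alone. Its median was -0.37 in replicate 1 and -0.07 in replicate 2.

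The counts in the stress and remaining cell-type lists stand beside 16.45% of all tested genes past the threshold. Of 7 hypoxia genes 1 rose, PDC1 by 1.03 (SE 0.17, adjusted p = 0.026), also 1 adjusted over the list alone. The hypoxia list had a median of 0.16 in replicate 1 and 1.35 in replicate 2 (adjusted p = 0.0333, and adjusted p = 0.729 with an estimated correlation), and it lost its call when both channels had to be well above background (adjusted p = 0.0605). Of 14 abscisic acid and dehydration genes 3 rose and 1 fell, with the same counts adjusted over the list alone, and RD26 fell by 1.43 (SE 0.14, adjusted p = 0.00825). Of 9 cold acclimation genes 1 rose, COR15A by 0.97 (SE 0.09, adjusted p = 0.00809), and 1 fell (2 and 1 adjusted over the list alone). The cold list's median was 0.46 in replicate 1 and -0.24 in replicate 2. Of 9 heat shock genes 1 rose, HSP70 by 1.01 (SE 0.09, adjusted p = 0.00723), also 1 adjusted over the list alone. None of these 3 lists passed (adjusted p = 0.904, 0.953 and 0.438). Of 12 xylem genes 1 fell, XCP1 by 0.46 (SE 0.09, adjusted p = 0.04), and 0 passed adjusted over the list alone. The xylem list was lower (adjusted p = 0.0116, and adjusted p = 0.703 with an estimated correlation) and lost its call with median centring and with the mutant in Cy3 alone. Its median was -0.06 in replicate 1 and -0.43 in replicate 2. Of 9 phloem genes 2 rose, also 2 adjusted over the list alone, with OPS up by 0.65 (SE 0.09, adjusted p = 0.0168), and the list did not pass (adjusted p = 0.0561), though it did under 9 of 20 other settings. Of 12 stomatal genes 1 fell, BASL by 0.44 (SE 0.08, adjusted p = 0.0363), with 0 adjusted over the list alone and list adjusted p = 0.18. None of 6 housekeeping controls passed, over all genes or adjusted over the list alone (list adjusted p = 0.786).

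**Figure D2:**
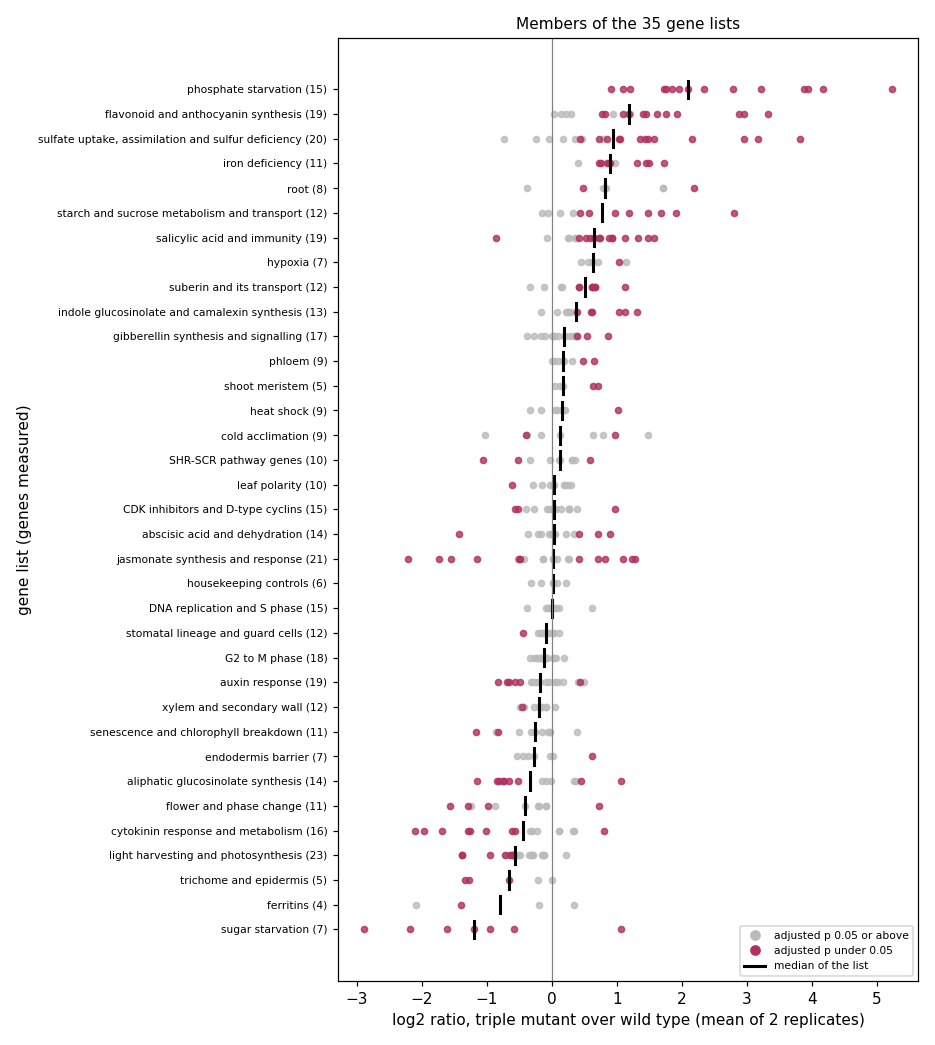
Log2 ratio of triple mutant over wild type (x axis, mean of 2 replicates) for the measured members of 35 gene lists (y axis, number measured in brackets, ordered by median). Red points passed the threshold, grey points did not, and black bars are list medians, from 2.102 for phosphate starvation to -1.195 for sugar starvation.

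Genes read by several probes showed a further difference. Of 6191 tested genes with 2 or more probes, 100 had probes whose log2 ratios differed by more than 1. Along the gene order of TAIR10.1, 21 of the 100 lay in 3 regions that together hold 305 tested genes: AT2G03390 to AT2G05810 on chromosome 2, and AT3G32930 to AT3G44716 and AT3G46040 to AT3G47340 on chromosome 3. RPS15AD, AT3G47250, PLC8, AT2G04378, ASN1 and LHCB2.1 are among the 21. Leaving out the 100 genes, a setting chosen after seeing the data, gave 3314 calls.

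**Figure D3:**
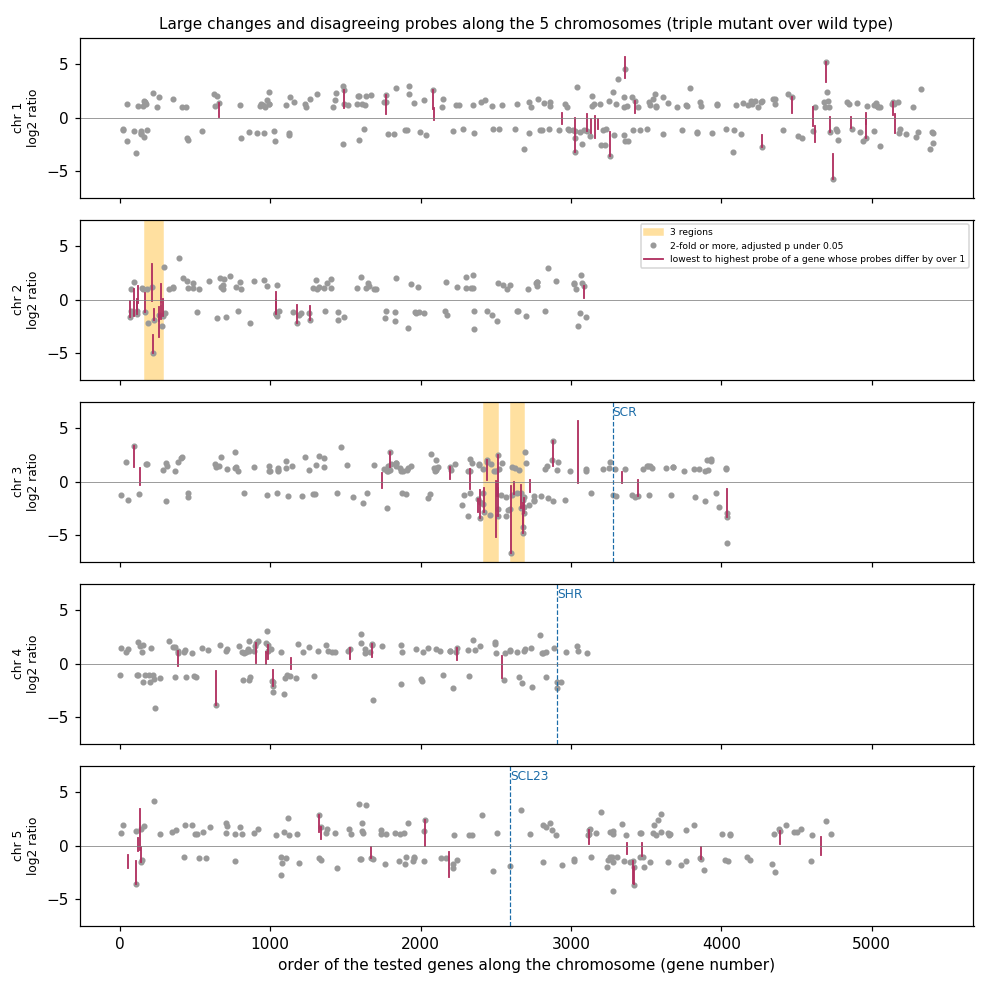
Log2 ratio of triple mutant over wild type (y axes) against the order of tested genes along the 5 chromosomes (x axis). Grey points are the 862 genes past the threshold and at least 2-fold different, red lines join the lowest and highest probe of the 100 genes whose probes differ by more than 1, and yellow bands are the 3 regions. Dashed lines mark SHR, SCR and SCL23, none of which lies in a band.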

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

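The tests on the phosphate list in this part were chosen after its values had been seen. Among 115 named genes and 35 list medians, 4 had 1 array far from the other 3. Chance at 1 in 20 would give about 7.5 among 150 groups if arrays and groups were independent. The arrays are paired by replicate and by dye, and the lists hold named genes, so that number is no fair measure of chance. The array was replicate 1 with the mutant in Cy5 each time. Without that array 1395 genes passed the threshold in place of 3377. ABCG20, a suberin-related transporter gene, read 0.91 there against 0.56 to 0.60 on the other arrays (gap over range 0.90). KRP7, a CDK inhibitor gene, read -0.61 against -0.51 to -0.49 (0.839). The median of the cytokinin list was -0.68 there and -0.38 to -0.37 elsewhere (0.945). The median of the stomatal list was -0.13 there and -0.09 elsewhere (0.95).

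Probes with no locus name here were outside the gene counts. Of 3152 such probes in the filter, 292 passed the threshold in a fit over all probes, 142 higher and 150 lower in the mutant, and 53 differed at least 2-fold on all 4 arrays.

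All 15 measured phosphate starvation genes rose in the mutant. The tables argue against dye bias, since the median was 2.24 on the arrays with the mutant in Cy5 and 2.01 with it in Cy3. Root tissue in the mutant sample could raise these genes too, and this stays open. The mean of the root list was 1.02 against 2.55 for the phosphate list (exact two-sided permutation p = 0.00584 over genes, which are not independent). Without background subtraction the means were 1.47 and 2.75 (exact two-sided permutation p = 0.0298). With processed signals the means were 2.37 and 2.91 (exact two-sided permutation p = 0.409), and the root list's median of 3.09 lay above the phosphate list's 2.39. The genotype itself and a difference in phosphate supply between the plants of the 2 genotypes were not tested.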

How the results depend on the processing

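The 24 highest and lowest genes and the 3 targeted genes kept their direction under every setting that tested them, and the targeted genes kept their calls in each test. Each of these genes had 1 sign on all 4 arrays, by choice for the 24. Settings that leave out or split arrays could therefore not reverse them. The count of 3377 genes past the threshold moved to 2212 with processed signals and loess, 2113 with Agilent's processed log ratio, 1883 with no filter on dim probes (more genes tested), 5703 with 4 arrays and the replicate block as a random effect, 6565 with no replicate block, 5454 at adjusted p 0.10 and 6977 at unadjusted p 0.05. A fixed replicate block with a dye term, chosen after seeing the data, gave 13717. That fit takes the difference between replicates out of the error, so its calls are not measured against the spread between replicates. Leaving out single arrays gave 1395 to 2702. The count of 448 genes at least 2-fold different on all 4 arrays moved to 1271 with processed signals and loess, 747 with no background subtraction, 1247 with Agilent's log ratio, 1255 with the authors' value table and 870 on the 2 arrays with the mutant in Cy5. Leaving out arrays or a replicate gave 463 to 814, with fewer arrays to pass. Of 35 lists, 19 passed. By camera with an estimated correlation, which had little power with 1 residual degree of freedom, 0 passed. Directional fry passed 0 and mixed fry 4. These 4 were the suberin, sugar starvation, flavonoid and gibberellin lists, the last of which had not passed by camera. In 20 other settings of values or fit 15 to 21 passed, and 11 of the 19 kept their calls in each. Phloem, meristem, gibberellin, auxin and ferritin lists, which had not passed, did so under 1 to 9 of the 20. Without genes saturated on any array, chosen after seeing the data, 18 passed, among them the same 11. The median of the root list ranged from 0.698 with median centring to 3.09 with processed signals and loess. Reversed values were a median of 0.21 for light harvesting with the mutant in Cy3 alone and -0.075 for PYK10 with it in Cy5 alone. Beyond the settings named, the cause was not tested. Replicates left out one at a time gave values with no test. Without replicate 1, 5 of 35 list medians moved by more than the spread between replicates, and 9 did so without replicate 2. That spread comes from 2 values and is smallest where the replicates are close, so these counts do not measure instability. The random block with a dye term could not be fitted, and slide as a block was not run, since all arrays share 1 slide. Dim probes limit the ratios: 48 genes were not well above background in the mutant on any array while above it in wild type on all 4, and 109 the other way round.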

Other observations

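None of the tests in this part was in the plan written before the data were examined. Most were chosen after the positions of strongly changed genes had been seen. Predictions on runs of adjacent genes and on the share of differing probes inside the region of large changes were written before those results. Those predictions did not include the draws matched by size of change. The last 4 tested genes of chromosome 3 were all lower in the mutant, and were singled out after their values were seen. CCD1 fell by 5.71 (SE 0.15, adjusted p = 0.00172), AT3G63510 fell by 3.29 (SE 0.11), BB, which limits organ size, fell by 2.88 (SE 0.11) and TTA2 fell by 0.92 (SE 0.09, adjusted p = 0.00899).

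FER, a receptor kinase gene, had a bright probe at -0.08 and another at 5.69, and the chaperone gene HSC70-1 had probes from -0.35 to 3.44. AT3G44430 had probes at 0.04 and -5.20. These 3 genes did not pass the threshold on the probe used.

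Large changes, that is genes past the threshold and at least 2-fold different, were gathered on chromosome 3 from AT3G45970 to AT3G48115, where 21 of 162 tested genes changed, 16 lower and 5 higher. The highest count in 100 neighbouring tested genes was 16, reached in 81 of 10000 shuffles of the calls, which argues against chance position. With each run of adjacent changed genes counted once, the highest count was 14, reached in 450 of 10000 shuffles. Directly adjacent genes changing together thus narrowly do not account for the whole. Copies with an unchanged tested gene between them were still counted separately, so copies changing together are not excluded. In this region 14.3% of genes with several probes had probes that differed by more than 1, against 1.51% outside. The 95th percentile for the region rotated along the genome was 7.84%. But large ratios bring differing probes anywhere. Among its large changes with several probes it was 5 of 8, against 25.9% of such changes outside. Genes outside matched by size of change gave at least as many in a share of 0.418 of draws. Sequence variants that change probe binding could thus be neither excluded nor shown here.

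Genes whose probes disagree lay together as well. The highest count in 100 neighbouring tested genes was 8, reached in 1 of 10000 shuffles among genes with several probes, which argues against chance position. The shuffle and the exact test below counted neighbouring genes as independent, and the shuffle was not matched by size of change. The region AT3G46040 to AT3G47340 also lies within the region of large changes above. A candidate explanation is that the mutant carries chromosome segments of another strain, in which probes made for the reference bind less well. The most extreme probe was lower in the mutant for 81.0% of the 21 such genes in the 3 regions and for 53.2% of the 79 elsewhere (Fisher's exact test, two-sided p = 0.0253). The regions were found in the same data, the labels name only Col-0, and genome sequence of the mutant was not analysed here, so this is a hypothesis.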
